A study of Macaca fascicularis with 16 samples.

How the data were processed

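Total RNA of endometrium from 16 postmenopausal female cynomolgus macaques, 4 per treatment arm, was hybridised to 1-colour Affymetrix arrays designed for the rhesus macaque, a related species. Per the labels' protocols, RNA was extracted with Tri Reagent, purified on RNeasy columns and inspected on a Bioanalyzer, and biotinylated cRNA was made with an Enzo kit in a single round of amplification. Arrays were matched to arms and numbers by the sample titles. The series design states that the animals were randomized, so that the samples of an arm are separate animals; their numbers are not said to pair animals across arms.

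The deposited values are intensity values on a linear scale, 1 per probe set and array, from 0.0242 to 23401 over 52865 probe sets. The submitters' processing notes name GCOS, Affymetrix Expression Console and MAS5, with no versions, and the scaling target is not given in the sources used here. MAS5 sets the match and mismatch probes of a set against each other and scales each array to 1 trimmed mean; the mean after leaving out 2% of values at each end was 250.0 on all 16 arrays, so the values were taken as scaled and were not normalized again. Such scaling removes differences in overall brightness, makes every change relative to the array's total, and leaves dim probe sets noisy. No present or absent calls were used here.

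The 99 control probe sets were left out of the tests. The values were taken to log2(signal + 4.80), where the pseudocount is the 10th percentile of all values; a change on this scale understates that of dim probe sets. The 40% of probe sets with the lowest mean over all arrays were left out without regard to arm, which left 31659 with a mean of at least 5.36 on the log2 scale. A linear model with a mean for each arm was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with 12 residual degrees of freedom shared by 7 comparisons, and eBayes with a trend of variance on signal. Adjusted p is Benjamini-Hochberg over all probe sets of a comparison, with a threshold of 0.05.

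Gene symbols came from the annotation of the array's platform, which gives 1 symbol to 24956 probe sets, several to 361 and none to 27449; a probe set with several was not named. A gene was followed through its probe set with the highest mean. Probe sequences were not used here, so cross-hybridisation of cynomolgus transcripts or of related genes was not examined, and no genome positions are given. Before the data were examined, 32 gene lists were fixed from textbook knowledge, with 772 symbols, of which 557 were annotated and 458 kept by the filter. The 29 lists with at least 5 genes left were tested with limma's camera at a preset correlation of 0.01, adjusted over these lists in each comparison, and again with the correlation estimated from the residuals; lists of steroid and estrogen metabolism, neutrophils and mast cells, and blood were too short. The calls that held with an estimated correlation were those of the estrogen-induced genes for estradiol and for the combination against control. A score is the mean over a list's genes of the deviation of the log2 value from the gene's mean over all arrays. limma's fry, which asks whether a list's genes move on balance one way, called 16, 8 and 11 lists for estradiol, tamoxifen and the combination against control, 4, 0 and 4 for the combination against estradiol, the combination against tamoxifen and tamoxifen against estradiol, and 8 for the interaction. The correlation of changes against the same controls was set beside that of unchanged groups simulated against them and beside one with the controls split between the comparisons. The overlaps of calls were set beside the same simulation and split, and the sharing with the estradiol arrays as reference likewise; both were chosen after seeing the data.

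The genes named were also fixed by rule: among genes past the threshold in which all 4 arrays of one arm lay above all 4 of the other, the 12 highest and 12 lowest changes in the comparisons with control and of the combination with each drug; the 5 highest and 5 lowest past the threshold for tamoxifen against estradiol and for the interaction; up to 4 members of each list with the smallest p; the 10 smallest p where fewer than 5 genes passed; and ESR1, PGR, GREB1, MKI67, TOP2A, IGF1, TFF1 and TFF3 throughout. TFF1 has no probe set under that symbol in the annotation. Outside the rule, PTTG1, HOXA13 and MYC with estradiol, DDIT3, LAMA2, TNC and DMBT1 with the combination, and NPY in the combination against tamoxifen, were chosen after their values were seen. No overlap between 4 and 4 arrays arises by chance in 2.86% of genes and was seen in 28.4%, 22.7% and 29.1% for estradiol, tamoxifen and the combination against control, in 10.4% for the combination and 7.12% for tamoxifen against estradiol, and in 2.92% for the combination against tamoxifen.

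The fit was tested on arrays simulated from the means and residual spreads of the real ones, with 200 of 31659 probe sets changed between estradiol and control. It recovered 8.96% of log2 changes of 0.5, 56.7% of changes of 1 and 90.9% of changes of 2, with 5 false calls of 109. Noise was drawn independently for each probe set, with no difference in quality or tissue makeup between arms, so these shares need not hold for the real arrays. A mitosis list shifted by 1 was called and 0 other lists were, in a step on 10705 genes simulated without correlation between them, so that step does not test the preset.

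The alternatives fixed before the data were examined were pseudocounts of 1 and of the 25th percentile, quantile normalization, no filter and a filter of 60%, eBayes without the trend, array weights (statmod 1.5.0), the array number as a block, fits to the 2 arms compared, an estimated correlation, the other probe sets of a gene, and leaving out each array in turn. The fits without estradiol 4 and tamoxifen 1, and with the smooth muscle score as a covariate, were added after seeing the data.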

Results

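Endometrium of 16 postmenopausal female cynomolgus macaques (Macaca fascicularis, an Old World monkey with menstrual cycles like those of women) was profiled after 4 months of treatment, with 1 expression array per animal. The animals had been randomized to 4 parallel arms of 4: placebo, called control here; micronized estradiol at 0.25 mg per 1800 kcal of diet; tamoxifen, a selective estrogen receptor modulator used against breast cancer, at 20 mg per 1800 kcal; or both drugs at these doses, called the combination. The design asks what each drug does to the endometrium of an animal without ovarian hormones, and what tamoxifen does when given with low-dose estradiol. The arrays were scaled to a common level before deposit, with a trimmed mean signal of 250.0 on every array. Median signals ran from 58.7 to 70.3. The number of arrays, 4 per arm, limits the precision. Every change is given as a difference of mean log2(signal + 4.80), with its standard error (SE) from limma, in a fit to all 16 arrays. Of 31659 probe sets tested, 18311 carried a single gene symbol, and 10705 genes were each followed through their brightest probe set.

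Arrays of one arm correlated with each other at a median r of 0.962, and arrays of different arms at 0.936, across probe sets, which are not independent replicates. Some arrays stood apart in tissue makeup. The smooth muscle marker score, the mean log2 deviation of 18 muscle genes from their mean over all arrays, was -2.72 in estradiol 4 and -0.75 in tamoxifen 1, and lay between 0.0096 and 0.29 in the controls. The epithelium marker score was 0.95 and 0.85 on these 2 arrays, the highest of their arms. Control 2 had the highest type I interferon score of its arm, at 0.68, and tamoxifen 3 that of its own, at 0.97. The log2 ratio of 3' to 5' signal of the actin control probe sets, a sign of RNA integrity and amplification, averaged 0.92 ± 0.11 (SD, n = 4) in the controls and 0.57 ± 0.18, 0.52 ± 0.043 and 0.55 ± 0.075 with estradiol, tamoxifen and the combination. In two-sided exact permutation tests against the controls these 3 differences had p = 0.0571, 0.0286 and 0.0286, where 0.0286 is the smallest p possible, and 0.0779, 0.0714 and 0.0714 after Benjamini-Hochberg adjustment over 15 such tests. The same ratio of the GAPDH probe sets differed from control by -0.16, -0.17 and -0.087 in these arms (exact p = 0.0571, 0.0286 and 0.0571), and that of the EF1a probe sets by 0.049, -0.028 and 0.0070 (exact p = 0.0571, 0.257 and 0.971).

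The comparison of estradiol with placebo asks how the tissue responds to the hormone without tamoxifen. The mean epithelium score was -0.77 in the controls and 0.28 with estradiol, so a change in level may also come from cell shares. With camera's preset correlation, mitosis, DNA replication, estrogen-induced, epithelium and extracellular matrix genes were called higher as groups with estradiol, and immediate early genes lower. With an estimated correlation the estrogen-induced list alone passed, at adjusted p = 0.0430, and the other 5 had adjusted p from 0.276 to 0.458. Of the genes whose arrays did not overlap between the 2 arms, DMBT1, a mucosal scavenger-receptor glycoprotein, rose most, by 4.70 (SE 0.46, adjusted p = 2.25e-05) on the log2 scale. Among the cell-division genes TOP2A, the topoisomerase of dividing cells, rose by 3.28 (SE 0.65) and MKI67, which encodes the proliferation antigen Ki-67, by 1.50 (SE 0.28). The estrogen-induced genes PGR, the progesterone receptor, IGF1 and GREB1 rose by 1.26 (SE 0.22), 1.26 (SE 0.18) and 1.06 (SE 0.29). FIBIN was lowest, 12.4-fold below control at a log2 change of -3.63 (SE 0.86), followed by CCL11, the eosinophil chemokine eotaxin, at -3.50 (SE 1.07, adjusted p = 0.0261).

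The 12 genes with the highest changes among those whose arrays did not overlap between the arms were DMBT1, CPM, ZWINT, DMKN, TNC, ST6GAL2, MFSD2A, TOP2A, LGALS7B, NEFH, MME and MEPE, from 4.70 down to 3.13. CPM, a membrane carboxypeptidase, rose by 3.48 (SE 0.42), the kinetochore gene ZWINT by 3.48 (SE 0.44) and TNC, the matrix glycoprotein tenascin-C, by 3.33 (SE 0.40). MME, which encodes the endometrial stroma antigen CD10, rose by 3.17 (SE 0.43), while its other tested probe set stood at -0.067. The 12 lowest were FIBIN, CCL11, FBXO32, FABP4, TXLNB, STIMATE, THSD7A, RGS9, PID1, XPNPEP2, GPIHBP1 and CNTN5, from -3.63 to -2.48. FBXO32, a ubiquitin ligase of muscle atrophy, fell by 3.01 (SE 0.53). FABP4, the fatty acid binding protein of adipocytes and capillaries, fell by 2.94 (SE 0.98), and GPIHBP1, which holds lipoprotein lipase on capillary endothelium, had a log2 change of -2.49 (SE 0.30).

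Among the gene lists fixed beforehand, 15 of 21 measured mitosis genes rose, 1 fell and 5 did not pass (15 higher and 1 lower adjusted over the list alone), with the motor gene KIF4A at 2.29, cyclin B2 (CCNB2) at 3.09 and PTTG1, the securin gene, as the one that fell, at -0.95, with its brightest other probe set at 1.72. The list had camera adjusted p = 1.17e-05, and adjusted p = 0.276 with an estimated correlation. Of 20 DNA replication genes 13 rose and 1 fell (14 higher and 1 lower adjusted over the list alone), the helicase gene MCM2 at 1.00 and the polymerase subunit gene POLE2 at -0.44, whose brightest other probe set stood at 0.42, with camera adjusted p = 0.000111, and adjusted p = 0.298 with an estimated correlation. Estrogen-induced genes rose in 12 of 21 (13 higher and 0 lower adjusted over the list alone), including IHH, the epithelial hedgehog ligand, at 2.27 and MYB at 1.92, with camera adjusted p = 0.00107, and adjusted p = 0.0430 with an estimated correlation. Epithelium markers rose in 10 of 16 (12 higher and 0 lower adjusted over the list alone), with KRT8 at 2.10 (camera adjusted p = 0.000740, and adjusted p = 0.458 with an estimated correlation). The mucous and secretory genes AGR2 and GCNT3 rose by 2.67 and 2.76, among 6 of 15 that rose (7 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0128, and adjusted p = 0.381 with an estimated correlation).

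Extracellular matrix genes rose in 13 of 25 and fell in 0 (14 higher and 0 lower adjusted over the list alone), with COL1A1 at 2.06, COL15A1 at 1.35 (brightest other probe set -0.092) and the collagen cross-linking enzyme LOXL2 at 2.33 (camera adjusted p = 6.70e-05, and adjusted p = 0.276 with an estimated correlation). Stroma fibroblast markers rose in 9 of 18 (10 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00443, and adjusted p = 0.276 with an estimated correlation), with THY1 at 1.78 and SFRP4, a secreted Wnt antagonist, at 1.44. Müllerian development genes rose in 9 of 19 and fell in 2 (9 higher and 3 lower adjusted over the list alone), with WNT5A at 1.80, HOXA11 at 0.76 and HOXA13 at -2.47 (camera adjusted p = 0.0372, and adjusted p = 0.276 with an estimated correlation), and without control 2 or estradiol 3 the camera adjusted p was 0.0635 or 0.0548. Unfolded protein response genes rose in 9 of 16 and fell in 2 (10 higher and 2 lower adjusted over the list alone); the protein disulfide isomerase PDIA6 rose by 1.23 (camera adjusted p = 0.00937, and adjusted p = 0.276 with an estimated correlation). Cholesterol synthesis genes rose in 7 of 16 (7 higher and 0 lower adjusted over the list alone), CYP51A1 by 1.27 (camera adjusted p = 0.00699, and adjusted p = 0.419 with an estimated correlation).

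Immediate early genes fell in 7 of 18 and rose in 1 (1 higher and 7 lower adjusted over the list alone), with FOS at -2.26 and DUSP1, a MAP kinase phosphatase gene, at -1.20, while MYC rose by 1.06 (camera adjusted p = 0.00576, and adjusted p = 0.276 with an estimated correlation). Endothelium markers fell in 9 of 20 and rose in 2 (2 higher and 9 lower adjusted over the list alone), with the sialomucin gene EMCN at -1.02 and SOX17, also a gene of uterine glands, at 1.79 (camera adjusted p = 0.0152, and adjusted p = 0.552 with an estimated correlation). Without estradiol 4 the endothelium camera adjusted p was 0.0529. Type I interferon genes fell in 5 of 19 and rose in 1 (1 higher and 6 lower adjusted over the list alone), with IFIT1 at -1.36 (camera adjusted p = 0.0414, and adjusted p = 0.610 with an estimated correlation). Their score was 0.29 ± 0.27 (SD, n = 4) in the controls, where control 2 lay highest, and without that array the camera adjusted p was 0.165; it was 0.0567, 0.0719 and 0.0523 without estradiol 2, 3 and 4. Smooth muscle markers fell in 2 of 18 (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0367, and adjusted p = 0.610 with an estimated correlation). Without control 3, control 4 or estradiol 4 alone the muscle list's camera adjusted p was 0.0501, 0.0531 or 0.881, and without estradiol 4 and tamoxifen 1, left out after seeing the data, the camera adjusted p was 0.882, with the direction turned. Outside the called lists the epidermal growth factor receptor EGFR rose by 1.84 (SE 0.19), IGFBP2 by 1.58 (SE 0.15) and the retinoid-binding protein CRABP2 by 2.30 (SE 0.43). ESR1, the estrogen receptor alpha gene, at 0.54 (SE 0.21, adjusted p = 0.0691), and TFF3, at 0.021 (SE 0.36, adjusted p = 0.976), did not pass.

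In all, 8062 of 31659 probe sets passed limma's test for estradiol against control, 4176 higher and 3886 lower, among them 1766 genes higher and 1410 lower. Of 29 lists tested, 14 passed camera with its preset correlation and 1 with an estimated one. Of 68 genes named as past the threshold, 4 missed it in some of the 8 fits without 1 array: FABP4 in all 8, CCL11 and MEPE in 6 each and PTTG1 in 2, with adjusted p up to 0.103, 0.0781, 0.110 and 0.0716. TXLNB, near the filter on dim probe sets, was tested in only 4 of these fits and passed in them. Without estradiol 4 the changes of FIBIN, CCL11, STIMATE and CNTN5 were -2.71, -2.81, -2.02 and -1.77, and without estradiol 3 those of FIBIN, CCL11 and FBXO32 were -4.26, -4.43 and -3.65. The actin ratio was 0.57 in the estradiol arm and 0.92 in the controls.

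**Figure D1:**
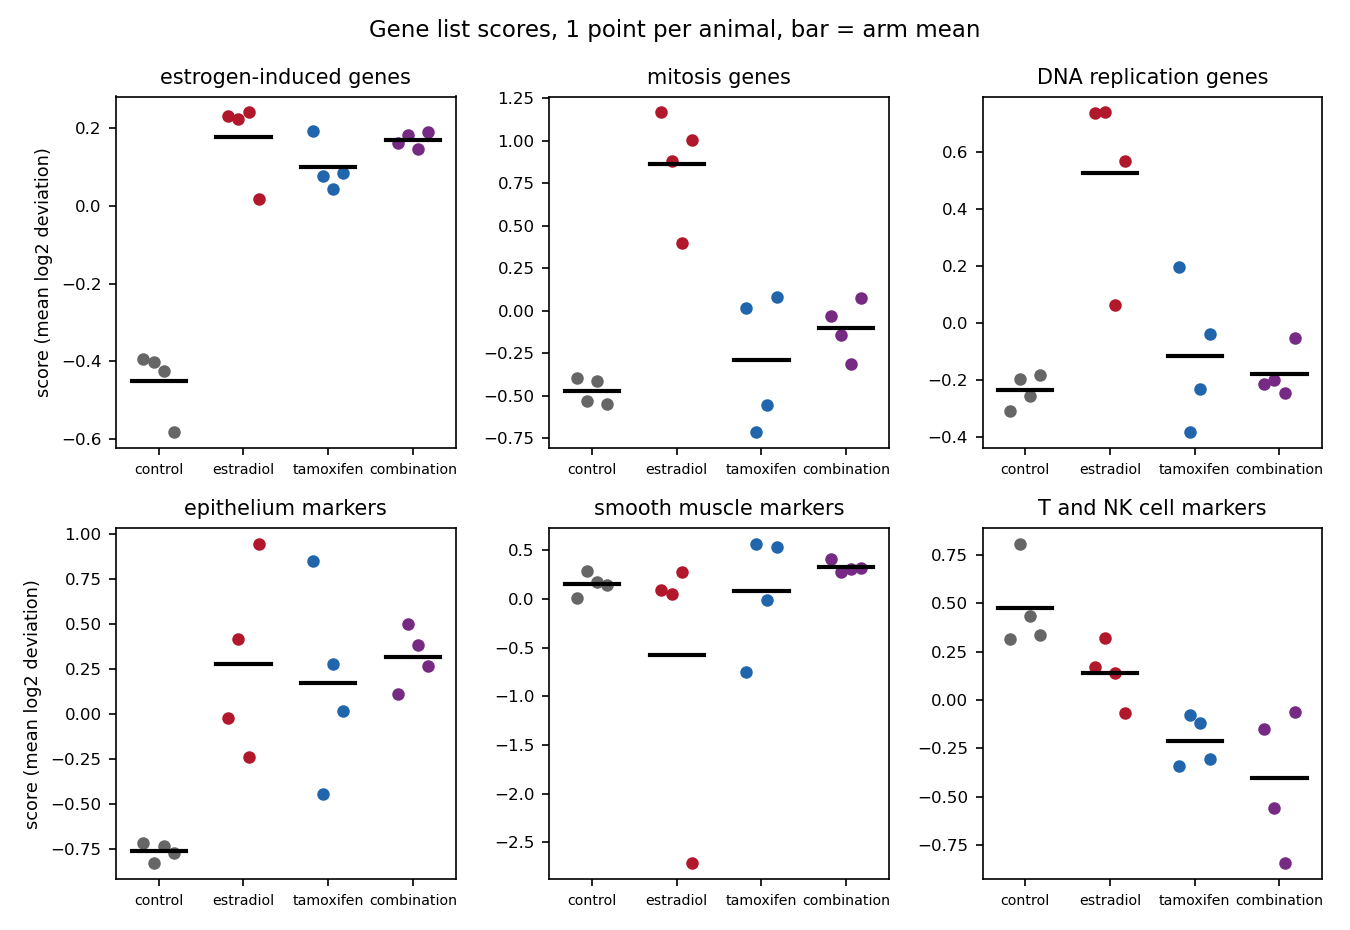
Score of 6 gene lists on each array (y axis: mean log2 deviation of the list's genes from their mean over all 16 arrays) by arm (x axis); points are single animals and bars are arm means. The mitosis score averaged 0.86 ± 0.33 (SD) with estradiol and -0.10 ± 0.17 with the combination, and the smooth muscle point of estradiol 4 lies at -2.72.

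The comparison of tamoxifen with placebo asks whether tamoxifen acts on this tissue without estrogen. With camera's preset correlation, epithelium, mucous, stroma and estrogen-induced genes were called higher as groups with tamoxifen, and T and NK cell markers lower. With an estimated correlation none of these 5 lists passed, with adjusted p from 0.0603 to 0.475. At the gene level 0 of 21 mitosis genes rose and 0 fell. The highest changes among genes without overlap between arms were those of NPY, which encodes neuropeptide Y, at 4.71 (SE 0.76, adjusted p = 0.00172), and of LGALS7B, an epithelial galectin, at 4.64 (SE 0.61, adjusted p = 0.000519). NPY was at 2.83 on the log2 scale in control 1 and between 5.91 and 6.12 in the other controls, and without control 1 its change was 3.91, below that of LGALS7B. CCL11 was lowest, at -3.56 (SE 1.07), followed by CNTN5 and then FIBIN at -3.23 (SE 0.86). CCL11 and FIBIN had been the lowest genes with estradiol, in a comparison with the same control arrays, so the rankings are not independent. HOXA13, a homeobox gene of the posterior body axis, fell by 3.10 (SE 0.52, adjusted p = 0.00192). MKI67 at -0.072 (SE 0.28, adjusted p = 0.897) and TOP2A at 0.71 (SE 0.65, adjusted p = 0.506) did not pass.

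The 12 highest genes were NPY, LGALS7B, NEFH, GMPPA, GJB6, MFSD2A, CPM, GCNT3, ADGRG2, TFPI2, DMBT1 and LOC722315, from 4.71 to 2.99. NEFH, the neurofilament heavy chain, rose by 4.20 (SE 0.48), GJB6, the gap junction protein connexin 30, by 3.30 (SE 0.76), and DMBT1 by 3.08 (SE 0.46). The 12 lowest were CCL11, CNTN5, FIBIN, HOXA13, TXLNB, PLSCR4, GPR20, PID1, GABRB1, POU2AF3, PRLR and XPNPEP2, from -3.56 to -1.85. PRLR, the prolactin receptor, fell by 1.87 (SE 0.42). PGR and IGF1 rose by 0.85 (SE 0.22) and 1.26 (SE 0.18). GREB1 at 0.18 (SE 0.29, adjusted p = 0.722), ESR1 at 0.44 (SE 0.21, adjusted p = 0.180) and TFF3 at 0.84 (SE 0.36, adjusted p = 0.130) did not pass.

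Estrogen-induced genes rose in 7 of 21 (8 higher and 0 lower adjusted over the list alone), with IHH at 2.76 and MYB at 2.52 (camera adjusted p = 0.00289, and adjusted p = 0.0603 with an estimated correlation). Epithelium markers rose in 7 of 16 (12 higher and 0 lower adjusted over the list alone), with MUC1 at 1.83 (camera adjusted p = 0.000194, and adjusted p = 0.475 with an estimated correlation), and mucous and secretory genes in 7 of 15 (7 higher and 0 lower adjusted over the list alone), with AGR2 at 2.48 and LYZ, lysozyme, at 2.58 (camera adjusted p = 0.000194, and adjusted p = 0.335 with an estimated correlation). Of 11 ciliated cell markers 1 rose, AGR3 at 1.94 (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00703, and adjusted p = 0.579 with an estimated correlation). Tamoxifen 1 had the highest epithelium score of this arm, 0.85, and a ciliated score of 1.40; without it the camera adjusted p of the ciliated list was 0.0745. Stroma fibroblast markers rose in 6 of 18 (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00703, and adjusted p = 0.417 with an estimated correlation) and extracellular matrix genes in 8 of 25, with 1 lower (11 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00703, and adjusted p = 0.475 with an estimated correlation). COL1A2, a chain of type I collagen on both lists, rose by 1.39. Unfolded protein response genes rose in 6 of 16 and fell in 2 (7 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0137, and adjusted p = 0.417 with an estimated correlation, and camera adjusted p = 0.0617 without tamoxifen 3), PDIA6 by 0.73. T and NK cell markers fell in 5 of 14 (0 higher and 6 lower adjusted over the list alone), with the T-box factor EOMES at -1.16 and CD8A at -1.02 (camera adjusted p = 0.00289, and adjusted p = 0.417 with an estimated correlation). The retinoid genes CRABP2, RBP4 and CRABP1 rose by 2.74, 2.68 and 2.67, and FOXA2, a transcription factor of uterine glands, by 2.15.

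limma called 4214 probe sets for tamoxifen against control, 2262 higher and 1952 lower, and 920 genes higher and 818 lower. The actin ratio was 0.52 in the tamoxifen arm and 0.92 in the controls. Among 40 genes named as past the threshold, 7 missed it in some fit without 1 array: CCL11, FIBIN, XPNPEP2, CD8A, GPR20, PGR and TXLNB, each with its highest adjusted p without tamoxifen 1, from 0.0636 to 0.118. Without tamoxifen 1 the changes of CCL11 and FIBIN were -2.78 and -2.43, without tamoxifen 2 those of CCL11 and GMPPA -4.20 and 4.61, without tamoxifen 3 that of HOXA13 -2.48 and without tamoxifen 4 that of CCL11 -4.28. camera called 8 lists with its preset correlation and 0 with an estimated one. In a fit to these 2 arms alone the count was 2714, and without tamoxifen 1 it was 2714.

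The combination was set against placebo in the same way. LGALS7B rose by 5.70 (SE 0.61, adjusted p = 0.000114), NPY by 5.28 (SE 0.76, adjusted p = 0.000614) and NEFH by 4.57 (SE 0.48, adjusted p = 9.33e-05). Without control 1, low in NPY, the change of NPY was 4.48. HOXA13 fell by 3.14 (SE 0.52, adjusted p = 0.00136). CD8B, a chain of the CD8 co-receptor, had a log2 change of -1.71 (SE 0.25) and the granzyme gene GZMH of -1.99 (SE 0.38). MKI67 did not pass, at 0.12 (SE 0.28, adjusted p = 0.807).

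The 12 highest genes were LGALS7B, NPY, NEFH, CHRDL2, DLK1, GJB6, LOC722315, CPM, GCNT3, CRABP1, ADGRG2 and SRARP, from 5.70 to 3.51. CHRDL2, a secreted antagonist of bone morphogenetic proteins, rose by 4.29 (SE 1.02) and DLK1, an imprinted Notch-like ligand, by 4.16 (SE 0.92). The 12 lowest were HOXA13, CNTN5, GABRB1, PLSCR4, TXLNB, ADH7, PI16, FCER1A, RGS4, GZMH, KRT23 and GPR20, from -3.14 to -1.77. FCER1A, a chain of the high-affinity IgE receptor, fell by 2.05 (SE 0.45). IGF1 rose by 1.06 (SE 0.18) and TFF3, a mucosal trefoil peptide, by 1.54 (SE 0.36). PGR at 0.64 (SE 0.22, adjusted p = 0.0657), GREB1 at 0.11 (SE 0.29, adjusted p = 0.827), TOP2A at 1.25 (SE 0.65, adjusted p = 0.206) and ESR1 at 0.40 (SE 0.21, adjusted p = 0.207) did not pass.

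Mucous and secretory genes rose in 8 of 15 (9 higher and 0 lower adjusted over the list alone; camera adjusted p = 4.45e-05, and adjusted p = 0.215 with an estimated correlation), with AGR2 at 2.77 and WFDC2 at 2.29. Epithelium markers rose in 10 of 16 (10 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.000171, and adjusted p = 0.534 with an estimated correlation), with MUC1 at 2.21. Estrogen-induced genes rose in 8 of 21 (10 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00124, and adjusted p = 0.0461 with an estimated correlation), with IHH at 2.96 and CCND1, cyclin D1, at 1.34. Extracellular matrix genes rose in 9 of 25 and fell in 2 (11 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.000439, and adjusted p = 0.425 with an estimated correlation), with TNC at 2.37 and LAMA2, a laminin chain, at -0.92. Unfolded protein response genes rose in 6 of 16 and fell in 1 (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0260, and adjusted p = 0.503 with an estimated correlation), with PDIA6 at 0.83 and DDIT3, a stress-induced transcription factor, at -0.71. Cholesterol synthesis genes rose in 5 of 16 (5 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0265, and adjusted p = 0.603 with an estimated correlation), with STARD4 at 1.01. Ciliated cell markers rose in 1 of 11 (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0260, and adjusted p = 0.608 with an estimated correlation), AGR3 at 1.97. T and NK cell markers fell in 6 of 14 (0 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.000399, and adjusted p = 0.351 with an estimated correlation), with EOMES at -1.50 and NKG7, a granule protein of killer cells, at -1.49. Type I interferon genes fell in 4 of 19 (0 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0260, and adjusted p = 0.643 with an estimated correlation), HERC6 to -1.13, and without control 2, whose interferon score was highest, the camera adjusted p was 0.0906; it was 0.0676 and 0.0706 without combination arrays 2 and 3. Of the mitosis genes 1 of 21 rose, ZWINT by 1.66.

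For the combination against control limma called 5015 probe sets, 2548 higher and 2467 lower, with 1138 genes higher and 973 lower; the actin ratio was 0.55, and 0.92 in the controls. Without combination array 1 the count was 3120. Named and past the threshold were 43 genes, of which 5 missed it in some fit without 1 array: HERC6 (highest adjusted p = 0.129), LAMA2 (0.116), GPR20 (0.0778), TXLNB (0.0664) and ZWINT (0.0563). Without combination array 1 the changes of DLK1 and GJB6 were 3.38 and 4.57. camera called 9 lists, and 1 with an estimated correlation.

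**Figure D2:**
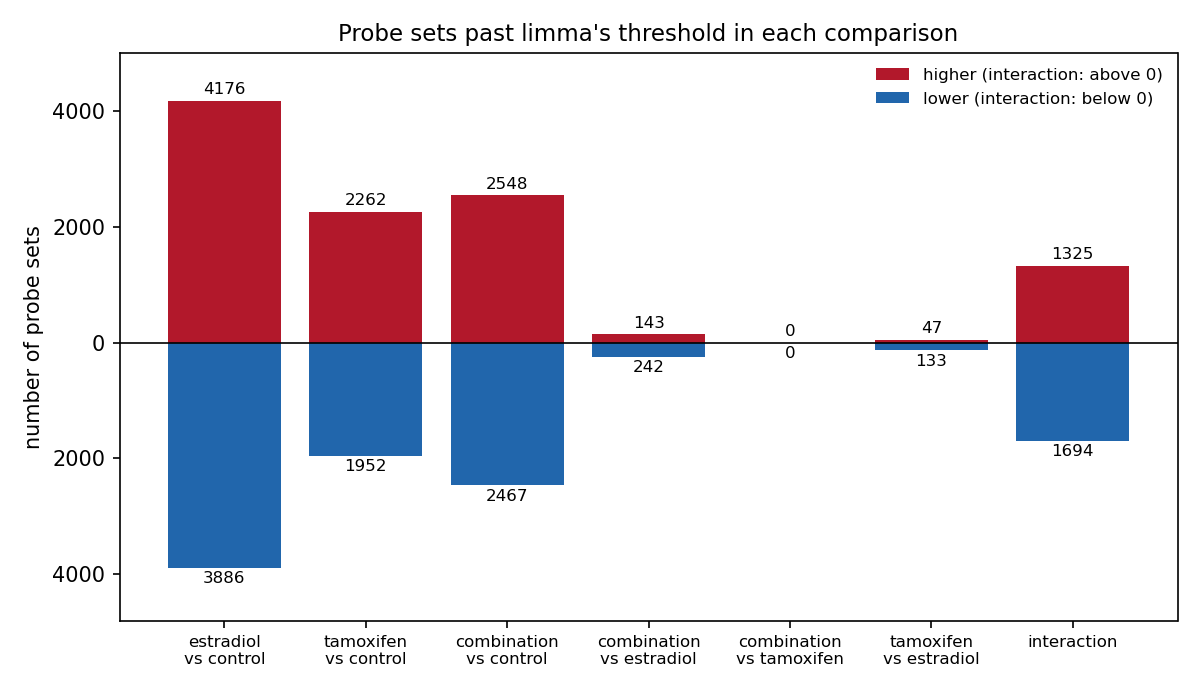
Number of probe sets past limma's threshold in each comparison (x axis), drawn upward for those higher and downward for those lower in the first-named arm, or above and below 0 for the interaction. The bars hold 4176 and 3886 probe sets for estradiol against control, and 0 for the combination against tamoxifen.

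Across genes, the changes from control under the 2 drugs were compared with each other. The correlation of the log2 changes over 10705 genes was r = 0.805; unchanged groups simulated against the same controls gave 0.498, and with the controls split 2 and 2 between the comparisons the observed value was 0.660. Genes are not independent replicates. The controls also had a higher mean actin ratio than each treated arm and a higher mean log2 signal of the hybridisation controls, 11.08 against 10.69, 10.85 and 10.82 with estradiol, tamoxifen and the combination, which neither the simulation nor the split takes out. Their mean epithelium score was lower, -0.77 against 0.28, 0.17 and 0.32 in these arms. So was their mean mucous and secretory score, -0.98 against 0.041, 0.34 and 0.60. A shift in cell shares common to the treated arms is not taken out either, and its part in the correlation was not tested. The covariance was 0.252 against a simulated 0.0283. Called higher with both drugs were 771 genes and lower 632, and 2 were called in opposite directions. Independent lists would share 152 and 108, and 20 simulated draws of unchanged groups against the same controls shared 0 and 0. Unchanged groups give few or no calls to share, so this 0 was fixed in advance. It does not tell how much of the overlap comes from the shared controls. With the controls split 2 and 2, which also leaves fewer arrays, 306 and 205 were shared on average over 6 splits, where independent lists would share 51.7 and 26.7. Tamoxifen and the combination correlated at 0.910, or 0.745 with split controls, and estradiol and the combination at 0.777, or 0.643.

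**Figure D3:**
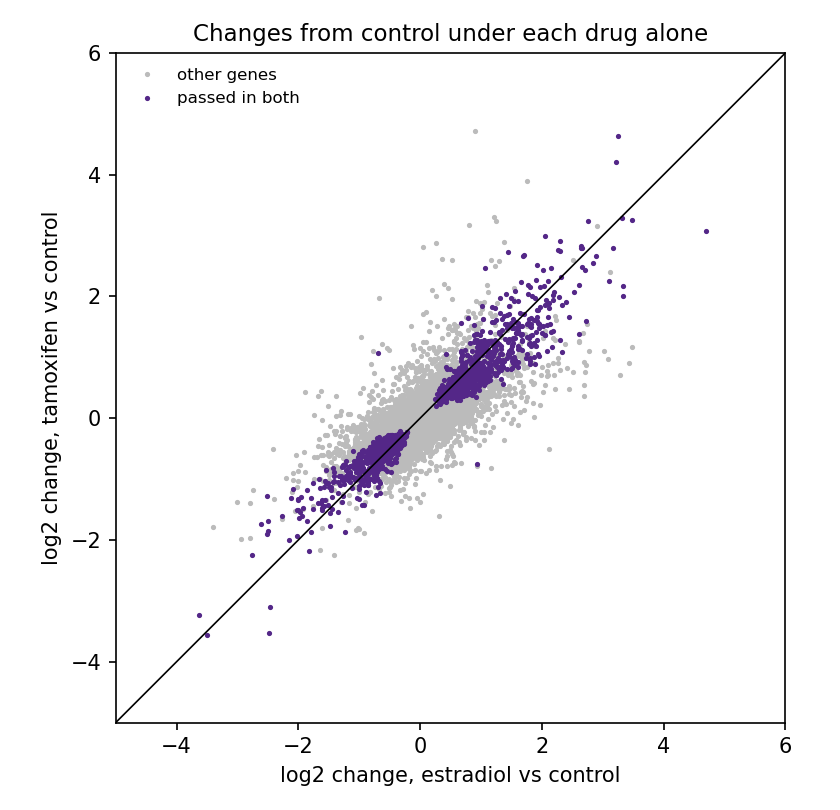
Log2 change against control with estradiol (x axis) and with tamoxifen (y axis) for each of 10705 genes; darker points passed limma's test in both comparisons, and the line marks equal change. The points follow a correlation of 0.805, part of which comes from the shared controls.

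The combination against estradiol asks what tamoxifen changes when added to the hormone. Mitosis and DNA replication genes were called lower as lists. This held with camera's preset correlation, and both lists had adjusted p = 0.235 with an estimated correlation. MKI67 had a log2 change of -1.37 (SE 0.28, adjusted p = 0.0341), the mitotic kinase gene CDK1 of -1.79 (SE 0.40), MCM2 of -0.96 (SE 0.14, adjusted p = 0.00847) and the proto-oncogene MYC of -1.23 (SE 0.20). The MKI67 adjusted p lay above 0.05 when any 1 array of the 2 arms but estradiol 3 was left out, and was 0.127 without estradiol 1, with log2 changes from -1.65 to -1.25. NPY was higher by 4.38 (SE 0.76, adjusted p = 0.0178) and CXCL17, a mucosal chemokine, by 3.13 (SE 0.33, adjusted p = 0.00253). SSTR1, a somatostatin receptor, had the lowest change, -3.12 (SE 0.66, adjusted p = 0.0358). TOP2A at -2.03 (SE 0.65, adjusted p = 0.131), PGR at -0.62 (SE 0.22, adjusted p = 0.186), GREB1 at -0.94 (SE 0.29, adjusted p = 0.113) and TFF3 at 1.52 (SE 0.36, adjusted p = 0.0520) did not pass.

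The 12 highest genes were NPY, CXCL17, LOC722305, ADGRG2, TAGAP, C11H12orf56, PADI2, GPC3, CFD, ITGA8, SCUBE2 and POPDC3, from 4.38 to 1.56; the brightest other probe set of LOC722305 stood at -1.49. CFD, the complement protease factor D, rose by 1.72 (SE 0.36). The 12 lowest were SSTR1, DMKN, IL1A, TGFBI, CDK1, CYP1B1, GFRA2, OLFML2B, ADAMTS19, TMSB15A, FN1 and NCAPG, from -3.12 to -1.47. IL1A, the cytokine interleukin 1 alpha, fell by 2.07 (SE 0.39); TGFBI, a matrix protein induced by TGF-beta, stood at -2.07 (SE 0.47) and FN1, fibronectin, at -1.47 (SE 0.30). ESR1 at -0.14 (SE 0.21, adjusted p = 0.809) and IGF1 at -0.20 (SE 0.18, adjusted p = 0.633) did not pass.

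DNA replication genes fell in 8 of 20 (0 higher and 13 lower adjusted over the list alone; camera adjusted p = 2.53e-10, and adjusted p = 0.235 with an estimated correlation), with CDC45 at -1.29. Mitosis genes fell in 7 of 21 (0 higher and 17 lower adjusted over the list alone; camera adjusted p = 2.53e-10, and adjusted p = 0.235 with an estimated correlation), with KIF4A at -1.43 and CENPF at -1.34. The mitosis score was 0.86 ± 0.33 (SD, n = 4) with estradiol and -0.10 ± 0.17 with the combination, while the epithelium score was 0.28 ± 0.52 and 0.32 ± 0.17. Extracellular matrix genes fell in 3 of 25 (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0414, and adjusted p = 0.684 with an estimated correlation), LAMA2 at -1.36. The matrix list's camera adjusted p was 0.0823 and 0.0501 without estradiol 1 and 2, and 0.0701, 0.0780 and 0.0922 without combination arrays 2, 3 and 4. Immediate early genes rose in 2 of 18 and fell in 1 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0146, and adjusted p = 0.468 with an estimated correlation, and camera adjusted p = 0.0542 without combination array 4), with DUSP1 at 0.73; MYC, also on this list, was the one that fell. T and NK cell markers lay lower as a list, with 0 of 14 past the gene-level test (0 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00388, and adjusted p = 0.468 with an estimated correlation). Mucous and secretory genes lay higher, with 0 of 15 past it (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0134, and adjusted p = 0.468 with an estimated correlation, and camera adjusted p = 0.0916 without estradiol 3). Endothelium markers, called higher as a list, held 1 gene of 20 past it, CLEC14A at -1.12 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0238, and adjusted p = 0.701 with an estimated correlation, and camera adjusted p = 0.209 without estradiol 4 and 0.0954 without combination array 3). Smooth muscle markers, called higher too, held 1 of 18, the integrin gene ITGA8 at 1.68 (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.000234, and adjusted p = 0.684 with an estimated correlation), and without the muscle-poor estradiol 4 the camera adjusted p of the muscle list was 0.209.

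Of 33 named genes past the threshold in this comparison 27, NPY among them, missed it in some fit without 1 array; CXCL17, GFRA2, MCM2, OLFML2B, SCUBE2 and TAGAP passed in all 8. SSTR1, near the filter on dim probe sets and tested in 5 of these fits, stood at -3.80 without estradiol 4. limma called 385 probe sets for the combination against estradiol, 143 higher and 242 lower, and 48 and 94 genes. The count was 47, 159, 1136 and 148 without estradiol 1, 2, 3 and 4, and 79, 65, 57 and 157 without combination arrays 1, 2, 3 and 4. With array weights it was 1687, with no filter on dim probe sets 221, and in a fit to these 2 arms alone 93.

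The combination against tamoxifen asks what estradiol changes when added to tamoxifen, and no probe set passed. limma called 0 of 31659, with 1283 at an unadjusted p under 0.05 where 1583 would be expected by chance, and a smallest adjusted p of 0.9999. The 10 genes with the smallest p, none of which passed, were PI16, POPDC3, MYL12A, MARK1, FKBP1B, C1H1orf115, TOM1L2, TRIQK, EBF1 and TSPAN31, with PI16 at -1.51 (SE 0.37) and POPDC3 at 1.10 (SE 0.29). The log2 changes of NPY, MKI67 and PGR were 0.57 (SE 0.76), 0.20 (SE 0.28) and -0.21 (SE 0.22), and those of IGF1, TFF3 and TOP2A -0.20 (SE 0.18), 0.69 (SE 0.36) and 0.55 (SE 0.65). ESR1 and GREB1 stood at -0.033 (SE 0.21) and -0.067 (SE 0.29). camera placed ribosomal protein genes and type I interferon genes lower, with 0 of 18 and 0 of 19 past the gene-level test, and none past it adjusted over the list alone. Ribosomal protein genes had a median log2 change of -0.17 and camera adjusted p = 0.00155, and adjusted p = 0.881 with an estimated correlation, and without tamoxifen 3 the camera adjusted p was 0.167. Interferon genes had camera adjusted p = 0.0103, and adjusted p = 0.881 with an estimated correlation, and without tamoxifen 3, whose interferon score stood apart, the camera adjusted p was 0.956, with the direction turned; it was 0.165 and 0.116 without combination arrays 2 and 3. A difference that misses the threshold with 4 arrays per arm is not shown to be absent.

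With tamoxifen set directly against estradiol, 7 of 21 mitosis genes were called lower, and a few genes led by NPY were called higher. The mitosis list passed with camera's preset correlation, and had adjusted p = 0.178 with an estimated correlation. NPY, CXCL17, WNT11, CFD and NGEF were highest with tamoxifen relative to estradiol, NPY by 3.81 (SE 0.76, adjusted p = 0.0364) and the ligand gene WNT11 by 1.75 (SE 0.22, adjusted p = 0.0151). CXCL17 was higher by 2.25 (SE 0.33). DMKN, ZWINT, IL1A, CKAP2 and KIF23 were lowest, ZWINT at -2.31 (SE 0.44) and the cytokinesis motor gene KIF23 at -1.75 (SE 0.33). MKI67 stood at -1.57 (SE 0.28, adjusted p = 0.0289), and passed in the fits without estradiol 3 and without tamoxifen 1 but in none of the other 6 that left out 1 array of the 2 arms. TOP2A at -2.57 (SE 0.65, adjusted p = 0.0944) and GREB1 at -0.88 (SE 0.29, adjusted p = 0.197) did not pass, nor did PGR at -0.41 (SE 0.22), ESR1 at -0.11 (SE 0.21), TFF3 at 0.82 (SE 0.36) and IGF1 at -0.0039 (SE 0.18).

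Of the lists, mitosis genes were lower in 7 of 21 (0 higher and 17 lower adjusted over the list alone; camera adjusted p = 2.86e-14, and adjusted p = 0.178 with an estimated correlation), with CENPF at -1.72. DNA replication genes were lower in 2 of 20 (0 higher and 11 lower adjusted over the list alone; camera adjusted p = 1.75e-09, and adjusted p = 0.239 with an estimated correlation), with MCM2 at -0.79. Extracellular matrix genes were lower in 2 of 25 (0 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.000239, and adjusted p = 0.281 with an estimated correlation), with LOXL2 at -1.23. Immediate early genes had 1 of 18 higher and 1 lower (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0176, and adjusted p = 0.442 with an estimated correlation), DUSP1 at 0.84 and MYC at -1.17. Endothelium and smooth muscle markers were placed higher by camera, and Müllerian development and cholesterol synthesis genes lower, with no member past the gene-level test. The endothelium list (0 higher and 0 lower adjusted over the list alone) had camera adjusted p = 0.00266, and adjusted p = 0.565 with an estimated correlation, and the smooth muscle list (1 higher and 0 lower adjusted over the list alone) camera adjusted p = 0.00275, and adjusted p = 0.565 with an estimated correlation. The Müllerian list (0 higher and 4 lower adjusted over the list alone) had camera adjusted p = 0.0187, and adjusted p = 0.241 with an estimated correlation, and the cholesterol list (1 higher and 2 lower adjusted over the list alone) camera adjusted p = 0.0187, and adjusted p = 0.565 with an estimated correlation. Without the muscle-poor estradiol 4 the smooth muscle direction turned, with a camera adjusted p of 0.948, and those of the endothelium and immediate early lists were 0.0504 and 0.0504. The cholesterol list's was 0.116, 0.0582 and 0.0540 without estradiol 1, 2 and 4.

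All 16 named genes past the threshold, NPY and CXCL17 among them, missed it in some fit without 1 array. limma called 180 probe sets, 47 higher and 133 lower with tamoxifen, and 16 and 60 genes. The count was 0, 73, 618 and 7 without estradiol 1, 2, 3 and 4, and 337, 2, 3 and 48 without tamoxifen 1, 2, 3 and 4. It was 0 in a fit to these 2 arms alone and 718 with array weights, and other splits of the same arrays gave counts as large.

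The interaction, the change from tamoxifen to the combination minus the change from control to estradiol, tests whether the effect of estradiol differed in the presence of tamoxifen. A change from control that is equal in all treated arms also gives an interaction, of the opposite sign. DMBT1 rose by 4.70 with estradiol, 3.08 with tamoxifen and 3.03 with both, an interaction of -4.74 (SE 0.65, adjusted p = 0.00163). ST6GAL2, MFSD2A, TGFBI and DMKN followed among the lowest, with ST6GAL2, a sialyltransferase gene, at -3.61 (SE 0.66). FIBIN, SNX15, FBXO32, SEMA3C and CNTN5 were highest, with FIBIN at 4.56 (SE 1.22, adjusted p = 0.0299) and FBXO32 at 3.41 (SE 0.75). PGR and IGF1 had interactions of -1.47 (SE 0.32, adjusted p = 0.0120) and -1.46 (SE 0.25, adjusted p = 0.00408). MKI67 at -1.30 (SE 0.40, adjusted p = 0.0516), TOP2A at -2.73 (SE 0.91, adjusted p = 0.0709) and GREB1 at -1.12 (SE 0.41, adjusted p = 0.0914) did not pass, nor did ESR1 at -0.58 and TFF3 at 0.67.

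**Figure D4:**
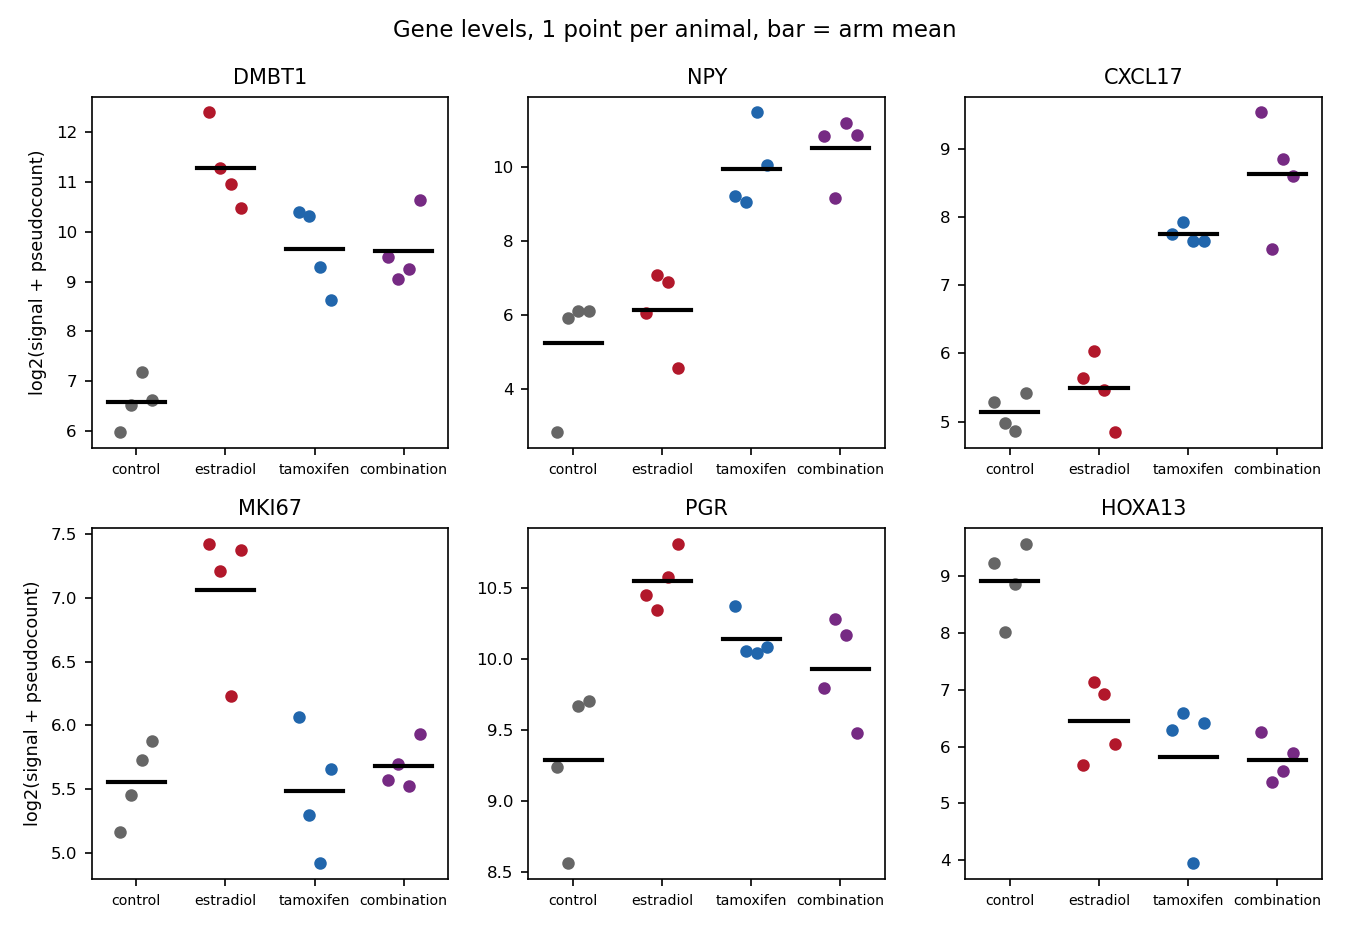
Log2(signal + 4.80) of 6 genes on each array (y axis) by arm (x axis); points are single animals and bars are arm means. NPY averages 6.15 ± 1.14 (SD) with estradiol and 10.52 ± 0.91 with the combination, and MKI67 7.06 ± 0.56 and 5.68 ± 0.18.

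Of 701 genes with an interaction below 0, 695 had passed as higher with estradiol alone and 466 with each drug alone; of 511 above 0, 497 had passed as lower with estradiol alone and 369 with each drug alone. These counts share arrays with the interaction. DNA replication genes had 6 of 20 below 0 and 1 above (1 higher and 13 lower adjusted over the list alone; camera adjusted p = 6.62e-05, and adjusted p = 0.289 with an estimated correlation), with MCM2 at -1.16. Mitosis genes had 8 of 21 below 0 (1 higher and 14 lower adjusted over the list alone; camera adjusted p = 6.62e-05, and adjusted p = 0.3001 with an estimated correlation), with KIF4A at -2.23. Extracellular matrix genes had 11 of 25 below 0 (0 higher and 12 lower adjusted over the list alone; camera adjusted p = 0.00107, and adjusted p = 0.289 with an estimated correlation), with COL1A2 at -1.65. Stroma fibroblast markers had 8 of 18 (0 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.00107, and adjusted p = 0.289 with an estimated correlation), with MME at -3.11. Estrogen-induced genes had 7 of 21 (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.00421, and adjusted p = 0.0970 with an estimated correlation), with IHH at -2.07. Epithelium markers had 1 of 16 (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00421, and adjusted p = 0.615 with an estimated correlation), KRT8 at -2.16. Unfolded protein response genes had 6 of 16 below and 2 above 0 (2 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.00771, and adjusted p = 0.289 with an estimated correlation), with PDIA6 at -1.12. Immediate early genes had 4 of 18 above and 1 below 0 (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00670, and adjusted p = 0.289 with an estimated correlation), with FOS at 2.32. Smooth muscle markers had none past the gene-level test (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0156, and adjusted p = 0.639 with an estimated correlation). Without estradiol 4 and tamoxifen 1 together the camera adjusted p was 0.567, with the direction turned, and without either alone it was 0.394 and 0.0698.

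FIBIN, CNTN5, SEMA3C, SNX15 and KRT8, 5 of 20 named genes past the threshold, missed it in some of the 16 fits without 1 array, with adjusted p up to 0.0566, 0.0665, 0.0763, 0.0780 and 0.0572. The interaction of FIBIN was 5.18, 3.63 and 3.76 without estradiol 3, estradiol 4 and tamoxifen 1, that of FBXO32 4.06 without estradiol 3, and those of CNTN5 and SEMA3C 2.49 and 2.43 without estradiol 4. SNX15 stood at 5.29, 4.93 and 3.65 without control 1, tamoxifen 1 and tamoxifen 3. limma called 3019 probe sets for the interaction, 1325 above 0 and 1694 below. The count was 1797 without estradiol 1, 1873 without estradiol 2 and 1871 without combination array 3.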

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

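For the mitosis genes the tests of the epithelial share and of single arrays, both smooth muscle tests, the covariate fits for tamoxifen, the combination and the genes called with both drugs, and the tests of RNA integrity and of brightness as the whole source of the changes were chosen only after the result was seen; the covariate fits for estradiol and of the epithelium score were chosen before. A sample was singled out where it lay apart from the other 3 of its arm by a gap that, as a share of the arm's range, was above Dixon's 95% critical value. Chance alone does this in about 1 of 20 groups: of 116 groups of list scores 10 were apart where 5.8 would be by chance, of 20 groups of quality measures 1 where 1 would be, and of 28 groups for the 7 genes followed throughout 2 where 1.4 would be.

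Mitosis genes were lower with the combination than with estradiol, by a median of -1.28 and a score difference of -0.97 (SE 0.19; two-sided exact permutation p = 0.0286, the smallest possible). A smaller epithelial share would need a lower epithelium score with the combination, and the score differed by 0.040 (SE 0.28; exact permutation p = 0.914). The score thus showed no drop, but its SE with 4 arrays per arm is too wide to exclude a smaller epithelial share. With the epithelium score of each array as a covariate the median was -1.31. The arm means of that score were 0.28 with estradiol and 0.32 with the combination, so the covariate could hardly move the median. The stroma score was 0.31 and 0.029 in these arms, and the stromal share was not tested. Without any 1 of the 8 arrays the median lay between -1.56 and -1.12, so no 1 array accounts for the difference. That tamoxifen holds back the proliferative response to estradiol in this tissue may be put as a hypothesis, found and tested on the same 16 arrays. It stays limited by the gene-level calls, which changed with single arrays, and by the estimated correlation, under which the list did not pass.

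Smooth muscle markers were lower with estradiol than in the controls, by a mean of -0.73, and the score of estradiol 4 was -2.72 where the other 3 arrays lay between 0.053 and 0.28. Within the estradiol arm this array also had the lowest stroma score, -0.0033, the lowest endothelium score, -0.50, and the highest epithelium score, 0.95. Its T and NK cell score, -0.068, and macrophage and monocyte score, -0.48, were the lowest too. Its B and plasma cell score, 0.73, was the highest of the arm. The stroma markers were higher with estradiol by a mean of 0.73 (SE 0.11), but that mean is over the whole arm and decides nothing about a smaller share of all tissue other than epithelium in estradiol 4. Without estradiol 4 and tamoxifen 1 the mean muscle difference was -0.013, which tests no explanation, since the arrays were picked by their muscle scores. Uneven pieces of tissue, a smaller share of all tissue other than epithelium and an effect of estradiol on muscle in that 1 animal all stay open.

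The mean 3' to 5' ratio of the actin control and the mean hybridisation signal were higher in the controls than in each treated arm, though the EF1a ratio differed from control by 0.049, -0.028 and 0.0070 with estradiol, tamoxifen and the combination, and either may account for part of the 8062 probe sets called for estradiol. With the actin ratio as a covariate 3133 were called, 2603 of them the same ones in the same direction, and with the hybridisation controls 2819, of which 2194 were the same. The median change of the original calls, in their direction, was 0.707 before, 0.707 with the ratio and 0.699 with the hybridisation controls, while the median SE went from 0.169 to 0.266 and 0.260. Calls were thus lost with a wider error and not with smaller changes. The slope of a covariate rests on differences within arms. The actin ratio had an SD of 0.043 to 0.18 there, against differences of -0.35 to -0.40 from control. Error in such a measure pulls the slope toward 0. The kept medians therefore do not decide whether either was the whole source of the estradiol calls. By the rule set beforehand, on the share of calls left, the estradiol counts did not decide either. For tamoxifen against control 192 of 4214 calls were left with the ratio and 1717 with the hybridisation controls, and for the combination 560 and 1917 of 5015, in the same direction. The median change of the original calls was 0.699 before, 0.663 with the ratio and 0.680 with the hybridisation controls for tamoxifen, and 0.703, 0.675 and 0.692 for the combination, while the median SE went from 0.168 to 0.286 and 0.205, and from 0.171 to 0.280 and 0.217. In the 1403 genes called in the same direction with both drugs the median change with tamoxifen was 0.646, 0.630 and 0.636, and with estradiol 0.745, 0.751 and 0.744, in the same order. These medians have the same limit. With the ratio 224 probe sets were called for tamoxifen, which the rule written for estradiol would count toward RNA integrity or amplification. The other counts would decide neither way under it. Neither measure can be told apart from treatment as a source of these calls, since both differ between control and treated arrays.

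The score of estrogen-induced genes was 0.019 in estradiol 4 against 0.22 to 0.24 in the other estradiol arrays, and its stroma score was -0.0033. Tamoxifen 1 had a mucous and secretory score of 1.17 and a PGR level of 10.38 on the log2 scale. The type I interferon score was 0.68 in control 2 and 0.97 in tamoxifen 3, whose unfolded protein response score was 0.12. The mean log2 signal of the hybridisation controls was 11.4 on control 2. TOP2A was at 7.06 in estradiol 3. Scores apart from their arms were also those of matrix proteases in control 3, -0.098, TGF-beta and BMP genes in combination array 2, -0.074, and retinoid pathway genes in combination array 1, -0.18.

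By the interaction itself, limma called a different effect of estradiol in the presence of tamoxifen for 3019 probe sets. The control arrays enter that difference, and their mean actin ratio and hybridisation signal were higher than in each treated arm. The covariate fits were not run for the interaction, so these measures cannot be told apart from treatment as a source of the calls. The mean epithelium score was -0.77 in the controls, against 0.28, 0.17 and 0.32 with estradiol, tamoxifen and the combination. A shift in cell shares common to the treated arms would enter the interaction too, and its part was not tested. With camera's preset correlation 9 lists passed for the interaction, and with an estimated correlation 0 passed. Of 100 splits of the arrays 15 gave as many lists.

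To see what other groupings give, the arrays of each comparison were split in all 35 ways into groups of 4, and for the interaction in 100 drawn ways, the real one included. Only the real split reached the 8062 probe sets of estradiol against control (highest other 45) and the 4214 of tamoxifen against control (1). The same held for the 5015 of the combination against control (0) and the 385 of the combination against estradiol (1). For each this is 1 of 35 splits, the smallest share possible and not adjusted over the counts tested. Chance is thus unlikely for these counts but not excluded. The real grouping was the only 1 of 100 to reach the 3019 of the interaction, with 537 as the highest other. These groupings mix all 4 arms and so undo the changes from control too. They leave open whether chance alone gives such an interaction. Chance is not excluded for the 180 of tamoxifen against estradiol, where 3 splits gave as many and the highest other gave 1810. For the combination against tamoxifen the real count was 0, which all 35 splits reach whatever the data, so that count decides nothing; the highest other gave 2. The split with 1810 set estradiol 1, 2 and 4 and tamoxifen 1 against estradiol 3 and tamoxifen 2, 3 and 4, a count many times the real one that points to a structure of the samples across these 2 arms. Of the list counts, the 14 lists of estradiol against control were reached by 1 of 35 splits, the real one, with 12 as the highest other. That is the smallest share possible, not adjusted over the counts tested, so it does not exclude chance for that count. Without 1 array the count was 11 to 14, and with an estimated correlation 1 list passed. Chance is not excluded for the 8 of tamoxifen and the 9 of the combination against control, where 5 and 4 splits gave as many, with 12 and 10 as the highest others. Nor is it for the combination against estradiol (8 lists, 8 splits, highest other 9) and, given in the same order, the combination against tamoxifen (2, 33, 11), tamoxifen against estradiol (8, 14, 11) and the interaction (9, 15, 13).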

How the results depend on the processing

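The fits without estradiol 4 and tamoxifen 1, and with the smooth muscle score as a covariate, were chosen only after the result was seen; the other tests of this part were chosen before. The counts of probe sets for estradiol, tamoxifen and the combination against control stayed within 1.5 times in both pseudocounts, quantile normalization, both filters, array weights and eBayes without the trend. Of 267 named gene values, 265 kept direction and side of the threshold under quantile normalization, 262 of 264 with a pseudocount of 1, 263 with that of the 25th percentile, 254 without the trend and 258 with array weights. Without a filter 20 no longer passed and none reversed, and of 191 left by the filter of 60% all 191 kept theirs. Of 58 list calls, 4 were lost under quantile normalization, 2 without a filter and 5 with array weights, and of 56 lists left by the stricter filter 6 were lost. camera was run without a variance trend throughout, and its own trend option was not tried. Without estradiol 4 and tamoxifen 1, 25 gene and 6 list calls were lost in the same direction, and with the smooth muscle covariate 22 and 9; in each fit 2 more list calls were lost with the direction turned.

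The count for the combination against estradiol was 221 without a filter, 1687 with array weights and 93 in a fit to these arms; for tamoxifen against estradiol it was 718 with array weights and 0 in such a fit, and for tamoxifen against control 2714 in such a fit, each of which rests on fewer arrays for the spread. The cause of the other moves was not tested. With an estimated correlation, 1 list passed for estradiol and 1 for the combination against control, and 0 in each other comparison. Without estradiol 4 and tamoxifen 1, 9 lists passed for the combination against tamoxifen. The correlation of the responses to estradiol and tamoxifen was 0.660 with the controls split, which takes out the shared arrays.

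Directions turned as follows, and the cause was not tested. The log2 change of ESR1 for the combination against tamoxifen was 0.023 with array weights and 0.090 without estradiol 4 and tamoxifen 1, that of GREB1 0.053 without these arrays, and that of IGF1 for tamoxifen against estradiol 0.055 with the smooth muscle covariate. The smooth muscle list turned without these arrays for estradiol against control (camera adjusted p = 0.882) and for the interaction (0.567), and with the covariate for the combination against estradiol (0.853) and for the interaction (0.759), where its own score was taken out. Of 91 named values with another tested probe set, 70 were the same in its brightest one. In that probe set 15 more no longer passed, in the same direction, and 1 passed only there. The directions opposed for COL15A1 (-0.092), MME (-0.067), POLE2 (0.42) and PTTG1 (1.72) with estradiol, and for LOC722305 (-1.49) in the combination against estradiol.

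Leaving out each array in turn gave 5931 to 8652 probe sets for estradiol, 2714 to 4055 for tamoxifen and 3120 to 4419 for the combination against control, 47 to 1136 for the combination and 0 to 618 for tamoxifen against estradiol, 0 to 1 for the combination against tamoxifen and 1797 to 4275 for the interaction. The list counts were 11 to 14, 7 to 8, 8 to 12, 6 to 9, 6 to 13, 0 to 9 and 8 to 11 in this order, with 0 and 9 lists for the combination against tamoxifen without tamoxifen 3 and without tamoxifen 1, and 13 for tamoxifen against estradiol without tamoxifen 2. Of 2318 gene values without 1 array, 1931 kept direction and call, 352 no longer passed and 21 turned. These were TFF3 with estradiol (-0.18 to 0.42), MKI67 with tamoxifen (-0.27 to 0.12) and the combination (-0.0065 to 0.23) and GREB1 with the combination (-0.12 to 0.33), all against control, ESR1 (-0.23 to 0.00076) and IGF1 (-0.13 to 0.12) for tamoxifen against estradiol, and ESR1 (-0.14 to 0.090) and GREB1 (-0.31 to 0.15) for the combination against tamoxifen, none of which passed on all arrays. The smooth muscle list for tamoxifen against estradiol had camera adjusted p from 5.86e-05 to 0.948, and the interferon list for the combination against tamoxifen from 3.88e-05 to 0.956.

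The array numbers are not said to pair animals: over 24 pairs of arrays with the same number the deviations from the arm means correlated at -0.266 to 0.0947 (median 0.00517), and 0 of 16 arrays correlated best with their own number. With the number as a replicate block the counts were 7397, 3735 and 4411 against control, 315 and 153 against estradiol, 0 for the combination against tamoxifen and 2609 for the interaction; 11 gene calls were lost and 3 gained. Of the lists 1 call was lost, interferon genes with estradiol (camera adjusted p = 0.0556), and 4 were gained: stroma for the combination against control (0.0369) and against estradiol (0.0323), and endothelium (0.0321) and cholesterol (0.0488) for the interaction. Dim probe sets stay limited by signal: those left out had means under 5.36 on the log2 scale.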

Other observations

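The lists of this part were fixed before the data were examined; the gene families, their definition and the tests of NPY, CXCL17 and the genes with them, by direction and by overlap, were chosen only after the result was seen. Several lists passed camera in no comparison. Wnt pathway genes rose in 8 of 28 and fell in 5 with estradiol (8 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.409), with the receptor genes FZD1 at 0.93 (SE 0.12) and FZD4 at -1.29 (SE 0.16). In the IGF axis 3 of 16 rose and 3 fell (3 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.955), with IGFBP2 at 1.58 (SE 0.15) and IRS2, an insulin receptor substrate, at -1.58 (SE 0.20). EGF family genes rose in 4 of 10 and fell in 1 (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.258), and retinoid pathway genes rose in 5 of 16 and fell in 2 (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.686), with RDH10, a retinol dehydrogenase, at 1.93 (SE 0.38). TGF-beta and BMP genes rose in 4 of 20 and fell in 4 (5 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.951), with BMPR1B, a receptor for bone morphogenetic proteins, at 1.49 (SE 0.32) and the co-receptor gene TGFBR3 at -1.24 (SE 0.22).

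Steroid receptors and cofactors rose in 5 of 15 and fell in 4 with estradiol (6 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.801), with the coactivator gene NCOA2 at -0.50 (SE 0.084). Progesterone-responsive secretory genes rose in 3 of 18 and fell in 3 (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.584), with IGFBP1, a marker of decidualized stroma, at -2.79 (SE 0.69), or -3.57 without estradiol 3, and HAND2, a stromal transcription factor, at 0.80 (SE 0.16). Matrix proteases and their inhibitors rose in 4 of 15 and fell in 1 (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.235), with MMP11, a stromal protease, at 2.72 (SE 0.42). Complement genes fell in 2 of 11 (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.155), with CD55, a decay-accelerating factor, at -1.86 (SE 0.32). B and plasma cell markers rose in 2 of 6 (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.245), macrophage and monocyte markers fell in 1 of 14 (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.440), and squamous markers rose in 1 of 6 (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.409).

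Genes were also grouped by the letters at the start of their symbols, in 148 families of at least 8 genes. With estradiol, 15 of 40 mitochondrial ribosomal protein genes named MRPL rose and 0 fell (camera adjusted p = 0.0173, and adjusted p = 0.696 with an estimated correlation). Of 252 zinc finger genes named ZNF, 60 fell and 13 rose with estradiol (camera adjusted p = 0.0112, and adjusted p = 0.696 with an estimated correlation), and 39 fell and 8 rose with the combination (camera adjusted p = 0.0141, and adjusted p = 0.694 with an estimated correlation). Of 8 MCM genes, 4 were lower with the combination than with estradiol (camera adjusted p = 0.000389, and adjusted p = 0.797 with an estimated correlation) and 1 with tamoxifen than with estradiol (camera adjusted p = 7.02e-05, and adjusted p = 0.966 with an estimated correlation). Of 24 RPL genes 0 passed for the combination against tamoxifen (camera adjusted p = 0.00129, and adjusted p = 0.899 with an estimated correlation). These families overlap the DNA replication and ribosomal protein lists.

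NPY and CXCL17 were higher in both tamoxifen arms than with estradiol alone, and 53 genes were called in the same direction in both of these comparisons, 12 higher and 41 lower. The comparisons share the estradiol arrays, and the calls of tamoxifen against estradiol changed with single arrays. Independent lists would share 0.0717 and 0.527, and 20 simulated draws of unchanged arms against the same estradiol arrays shared 0 and 0. Unchanged arms give few or no calls to share, so this 0 was fixed in advance and decides nothing. With the estradiol arrays split 2 and 2, 0.333 and 0.167 were shared on average over 6 splits, where independent lists would share 0.00540 and 0.00576. With fewer arrays 83.2 and 42 genes were called on average, so these counts do not tell how much of the overlap rests on the shared arrays. As a hypothesis, such genes could be set by tamoxifen itself and would then differ from control in both tamoxifen arms. Of all of them 26.4% did, of the higher ones 66.7% and of the lower ones 14.6%. For estradiol against control, 38 of the 41 lower ones were called higher, and 5 of the 12 higher ones were called in either direction. The genes were chosen on the same tamoxifen and estradiol arrays, so these shares and counts decide nothing and the question stays open.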
